A study of Drosophila melanogaster with 9 samples.

How the data were processed

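RNA was measured in the indirect flight muscle of 1 to 2 day old adult male Drosophila melanogaster raised at 25 °C, on 9 Affymetrix Drosophila Genome 2.0 arrays. Canton-S, a wild-type laboratory strain, was compared with Act88FKM88, a null allele of the flight muscle actin gene Act88F, and with Mhc7, an allele that removes myosin heavy chain from the flight muscle. Each genotype had 3 arrays, which the study describes as separate biological replicates and which are named here by genotype and replicate number, such as Canton-S 1. Per the labels, muscles were dissected from thoraces dehydrated in cold ethanol overnight, RNA was extracted with TRIzol, and 6 µg of total RNA was labelled as biotinylated cRNA.

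The authors deposited 1 expression value per probe set and array on the log2 scale, made by RMA (robust multi-array average, a method of background correction, normalization and summary over probes). Whether all 9 arrays were normalized together is not given in the sources used here, and their upper percentiles differ (95th percentile from 7.26 to 8.15), so the shares of higher and lower calls depend on the deposited scale. The log2 scale was checked on the range of the deposited values, and the RMA version is not given in the sources used here. Arrays carry no read depth, and their number limits the precision. The 18952 probe sets include 183 Affymetrix control probe sets, which were left out of the fits, so 18769 probe sets were tested with no filter on level. The platform annotation names 1 gene for 13647 of these, several genes for 402 and none for 4720, which gives 11983 genes. Where several probe sets name 1 gene, the probe set with the highest mean over the 9 arrays stood for the gene in gene lists.

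A linear model with a mean per genotype was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with a moderated variance. From it came the contrasts Act88FKM88 minus Canton-S, Mhc7 minus Canton-S and Act88FKM88 minus Mhc7, and a moderated F-test for any difference among the 3 genotypes. A probe set passed when its Benjamini-Hochberg adjusted p was under 0.1 and it changed at least 2-fold, the false discovery rate and fold that the study states. All p-values are two-sided unless stated otherwise. The verbs rose and fell are kept for what passed, and log2 differences carry the standard error of the contrast (n = 3 arrays per genotype). For single measures per array, such as percentiles, the exact permutation test of 3 against 3 arrays was used, whose smallest p is 0.1.

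The genes named in the text follow a rule set before the data were examined. It takes Act88F, the 10 probe sets with the largest rise and the 10 with the largest fall in each mutant among those past the threshold with 1 named gene and no overlap between the 2 genotypes, the 5 largest each way between the mutants, and up to 2 members per gene list and direction, or the 2 with the smallest p where none passed. Genes named outside that rule stand beside a small count and are said to have been chosen after their values were seen. Of 128 named-gene results past the threshold, 87 kept their call in all 9 fits that left out 1 array and 41 lost it in at least 1.

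In the same way, 35 gene lists were written by symbol before the data were examined, for sarcomere parts, protein quality control, energy metabolism, ribosomes, stress responses, and markers of other tissues that dissected muscle could hold. Each list with at least 5 measured genes was tested with camera in limma, which compares the list with all other genes, at a preset correlation of 0.01 between its genes, and was called at an adjusted p under 0.05. Each test was repeated with the correlation estimated from the data, and with fry (statmod 1.5.0), which tests whether the genes of a list move on balance one way. Members were counted after adjustment over all probe sets and, separately, adjusted over the list alone. Counts are of measured genes only. These were 9 of 23 inducible heat shock, 34 of 86 cytosolic ribosomal protein and 11 of 24 actin dynamics genes.

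The overlap of the mutants was set against independent lists of the same sizes and against 100 simulations with no effect in either mutant that kept the shared Canton-S arrays. Other settings, fixed before the data were examined, were stricter and looser thresholds, a test against 1.5-fold (treat), removal of probe sets below the 40th percentile of level, fits on the 6 arrays of each pair, SAM (written anew from its published description), array weights, a variance prior that follows intensity, centring on cytosolic ribosomal protein genes, repeated quantile normalization, the mean over all probe sets of a gene, a replicate block, and removal of each array in turn. Removal of each array's intensity trend by loess was added after the data were seen. The pipeline was tested on simulated data with known changes: 94% of 3-fold and 100% of 6-fold changes were recovered for Act88FKM88 against Canton-S, with 3 false calls. The simulated noise was independent between genes and held no scale difference between arrays, so these figures need not hold for the real arrays. No probe set carries the gene name Mhc, so the level of Mhc was not analysed here and the Mhc7 label could not be checked on its own gene.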

Results

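Deposited log2 RMA values were compared for flight muscle of Canton-S, Act88FKM88 and Mhc7 males, with 3 arrays per genotype. Median log2 values were 3.11 in Canton-S and 3.07 in both mutants, while the 95th percentile was 7.36 ± 0.11 (SD, n = 3) in Canton-S, 7.74 ± 0.20 in Act88FKM88 and 7.99 ± 0.20 in Mhc7. Both mutants lay above Canton-S at that percentile in every array (exact permutation p = 0.1 each, the smallest that 3 against 3 arrays allow). Across probe sets, arrays of 1 genotype correlated at r = 0.978 to 0.988 and arrays of different genotypes at 0.956 to 0.977. Among the 18769 probe sets, 1654 differed in some way among the 3 genotypes in the F-test, and 1092 did without Mhc7 3. The control probe set for 18S ribosomal RNA lay at 6.42 in Act88FKM88 3 and between 8.59 and 10.0 in the other arrays. Differences between 3' and 5' probe sets were largest in Canton-S 2, at 2.55 for GAPDH and 2.96 for eIF4a (1.68 to 2.13 and 2.12 to 2.58 in the others). Canton-S 1 had the lowest 99th percentile, at 11.08 against 11.61 to 11.89 in the other arrays. Abundant lists were lowest there too. Its mean was 9.63 for oxidative phosphorylation genes (10.04 to 10.18 in the others) and 10.00 for cytosolic ribosomal protein genes (10.52 to 10.83). Rises of such lists therefore lean on this array.

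Act88F, which encodes the actin of the indirect flight muscle (Entrez gene 41885), is the gene mutated in Act88FKM88. Its log2 level was 14.1, 14.3 and 14.4 in the Canton-S arrays, 11.6, 11.8 and 11.0 in the Act88FKM88 arrays, and 14.1, 14.2 and 14.1 in the Mhc7 arrays. In Act88FKM88 it fell by 2.80 ± 0.17 (SE, n = 3 per genotype; adjusted p = 8.25e-05), and the direct comparison with Mhc7 gave -2.70 ± 0.17 (adjusted p = 7.79e-05). The value in Mhc7 against Canton-S was -0.10 ± 0.17 (adjusted p = 0.858). Act88F was the highest value of each Canton-S array, at the top of the scale, and saturation there was not tested, so these differences can be compressed. Where the probes lie relative to the lesion was not determined.

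The comparison of Act88FKM88 with Canton-S asked which transcripts change in flight muscle that lacks its own actin. Proteasome subunits, which form the protease that degrades ubiquitinated proteins, had 13 of 26 measured members that rose and none that fell, with a median log2 difference of 1.03. The list had adjusted p = 8.87e-18 at the preset correlation, 0.536 with an estimated correlation and 0.0697 by fry, and 5 subunits rose without Canton-S 2 or without Act88FKM88 3. The core-particle subunit Prosbeta4 rose by 1.96 ± 0.27 and Prosalpha6 by 1.61 ± 0.30. The obscurin gene Obsc, whose product sits at the M-line of the sarcomere, fell by 3.47 ± 0.21, and the beta-tubulin gene betaTub97EF fell by 6.58 ± 0.13, from a log2 level of 9.85 to 3.28, near the median of all probe sets, so background limits the size of that fall. The Z-disc gene Zasp66 rose by 2.11 ± 0.13. Across the array, 340 probe sets passed, 278 higher and 62 lower in Act88FKM88, for 282 genes.

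Among the largest rises in Act88FKM88 were CG8768 (5.78 ± 0.36, adjusted p = 8.26e-05), the cytochrome P450 genes Cyp4e3 (4.36 ± 0.45, adjusted p = 0.0017) and Cyp6a20 (3.71 ± 0.28), the RNA polymerase I subunit gene Polr1E (3.83 ± 0.13, adjusted p = 1.45e-06), CG34324 (3.47 ± 0.47), CG7272 (3.40 ± 0.10), Arc1 (2.90 ± 0.44) and CG30197 (2.90 ± 0.29). Falls of similar size were seen for CG8788 (-3.64 ± 0.38, adjusted p = 0.0017), the kinase gene Hipk (-2.69 ± 0.27), CG5644 (-2.60 ± 0.30), CG42323 (-2.58 ± 0.44), Cyp4e1 (-2.49 ± 0.24) and gkt (-2.42 ± 0.13), which encodes a tyrosyl-DNA phosphodiesterase. Where 1 genotype lies near the array median, background limits the difference and the change can be larger: this holds for CG8768 (3.42 in Canton-S), Cyp4e3 (3.65), Polr1E (3.33), Cyp6a20 (3.04), CG34324 (3.54) and gkt (3.25 in Act88FKM88). Every call named up to here in this paragraph was kept in all 9 fits that left out 1 array. The apolipoprotein D homologue NLaz also rose (3.50 ± 0.89, adjusted p = 0.0807), a call lost without Canton-S 2, any of the 3 Act88FKM88 arrays, Mhc7 1 or Mhc7 3, with adjusted p up to 0.199. CG14645 rose by 3.35 ± 0.85 (adjusted p = 0.0792) and lost its call when any array except Act88FKM88 2 and 3 was left out, with adjusted p up to 0.207.

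Of the 35 gene lists, 15 were called in Act88FKM88, 14 higher and 1 lower than other genes, and none at an estimated correlation (lowest adjusted p = 0.536 with an estimated correlation) or by fry. The proteasome list had camera adjusted p = 8.87e-18, and 15 subunits passed when adjusted over the list alone. Its count of 13 became 6 without Canton-S 1, 5 without Canton-S 2 and 5 without Act88FKM88 3, and 3 when quantile normalization was repeated, where the list stayed called (median 0.71, adjusted p = 1.03e-08). Ubiquitin and ubiquitin ligase genes were also called (2 of 14 rose, median 0.35, adjusted p = 0.00875 and 0.536 with an estimated correlation), with the polyubiquitin gene Ubi-p5E at 1.36 ± 0.20; 1 rose without Canton-S 1 (median 0.23), Act88FKM88 1 or Act88FKM88 3. Among autophagy genes 1 of 25 rose (2 adjusted over the list alone; list adjusted p = 0.00868 and 0.536 with an estimated correlation). That gene, Atg8a (1.16 ± 0.21), lost its call without Canton-S 1, and 2 genes rose without Canton-S 3 or Act88FKM88 2. Constitutive chaperones were not called (adjusted p = 0.828), and 1 of 23 rose and 1 fell: Trap1, the mitochondrial Hsp90, fell by 1.61 ± 0.20. The member that rose, DnaJ-H (1.08 ± 0.25, adjusted p = 0.0589), lost its call without Canton-S 1, Canton-S 2, Act88FKM88 2 or Act88FKM88 3 (adjusted p up to 0.170) and with quantile normalization repeated (0.88). Of 23 inducible heat shock genes only 9 were measured. Among these 1 rose, stv (1.24 ± 0.32, adjusted p = 0.0811), a call kept only without Act88FKM88 3 or Mhc7 2 (adjusted p up to 0.248). Of 18 endoplasmic reticulum stress genes 1 rose, the kinase gene PEK (1.70 ± 0.44, adjusted p = 0.0863; 2 adjusted over the list alone; list adjusted p = 0.00868 and 0.536 with an estimated correlation). PEK lost its call without Canton-S 1, Canton-S 3, any Act88FKM88 array or Mhc7 1 (adjusted p up to 0.255), and 2 members rose without Mhc7 2.

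In the sarcomere lists of Act88FKM88, 2 of 15 Z-disc and myofibril assembly genes rose, Zasp66 and the muscle LIM protein gene Mlp60A (1.23 ± 0.17; list median 0.29, 0.19 without Canton-S 1, adjusted p = 0.00805 and 0.610 with an estimated correlation). The thick and connecting filament list was called higher than other genes (12 measured, median 0.30, adjusted p = 0.0411 and 0.662 with an estimated correlation), although its only member past the threshold was Obsc, which fell, and the list turned to the lower side with quantile normalization repeated (adjusted p = 0.944). That call was lost without Canton-S 1, Act88FKM88 1 or Act88FKM88 2, with adjusted p up to 0.319. A second probe set for Obsc gave -0.64. Thin filament genes were not called (adjusted p = 0.248), and Act88F was the 1 member of 12 that fell. The value of Act87E, another actin gene, was 0.96 ± 0.67 (adjusted p = 0.579). Among 14 regulators of flight muscle fate, not called as a list (adjusted p = 0.591), the spalt-related gene salr rose by 1.08 ± 0.14, and without Canton-S 3 its call was lost (0.94). Isoforms of other muscle types had a median of 0.96 over 5 genes, with none past the threshold.

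Antimicrobial and immune effector genes were called higher in Act88FKM88 (3 of 26 rose, 5 adjusted over the list alone; adjusted p = 0.00875 and 0.610 with an estimated correlation). The Drosomycin-like genes Drsl5 and Drsl3 rose by 1.88 ± 0.26 and 1.87 ± 0.21. With quantile normalization repeated the list had adjusted p = 0.0531, and with intensity trends removed 0.0381. Detoxification genes were called as well (6 of 52 rose, 8 adjusted over the list alone; adjusted p = 0.015 and 0.610 with an estimated correlation), led by Cyp4e3 and Cyp6a20, and the call was lost without Canton-S 2 (adjusted p = 0.0686). In the calcium list 3 of 17 genes rose, among them the sodium-calcium exchanger gene Calx (1.39 ± 0.20), with list adjusted p = 0.0336 and 0.654 with an estimated correlation. The calcium call was lost without Canton-S 1, Canton-S 2, Act88FKM88 2 or Mhc7 2 (adjusted p up to 0.276). In the list of JNK and cell death genes, not called, the Fos gene kay was the 1 of 19 that rose (1.38 ± 0.14). Of 18 antioxidant genes 2 rose, 0 without Canton-S 1, Canton-S 2 or Act88FKM88 1 and 1 without Canton-S 3, Act88FKM88 3, Mhc7 2 or Mhc7 3, with list adjusted p = 0.0678.

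Mitochondrial ribosomal protein genes were called higher in Act88FKM88 (7 of 69 rose, 8 rose and 1 fell adjusted over the list alone; median 0.43, adjusted p = 4.82e-07 and 0.690 with an estimated correlation), with mRpL33 at 1.55 ± 0.21, but the call ended with quantile normalization repeated (0 rose and 3 fell, median -0.00, adjusted p = 0.994). The count of 7 became 2 without Canton-S 1, 3 without Canton-S 2, 3 without Act88FKM88 1, 1 without Act88FKM88 2, where 3 fell, and 12 without Act88FKM88 3; the median was 0.21 without Canton-S 2 or Act88FKM88 2. Cytosolic ribosomal protein genes had a median of 0.43 with 0 of 34 past the threshold (median 0.21 without Canton-S 1; adjusted p = 1.1e-08, 0.638 with an estimated correlation, 0.124 with intensity trends removed, and 0.00116 with quantile normalization repeated, where the median was 0.09), among them RpLP0 at 0.69 ± 0.17 (adjusted p = 0.0668). Glycolysis and glycogen genes (2 of 20 rose, median 0.15, adjusted p = 0.00171 and 0.647 with an estimated correlation), tricarboxylic acid cycle genes (0 of 13, median 0.22, adjusted p = 0.00605 and 0.662) and oxidative phosphorylation genes (1 of 73, median 0.15, adjusted p = 0.00868 and 0.692) were called higher, and all 3 turned to the lower side of other genes with quantile normalization repeated (adjusted p = 0.931, 0.703 and 0.0531). With intensity trends removed all 3 turned as well, and the last 2 were called lower than other genes (adjusted p = 0.242, 0.0381 and 2.64e-10). UGP, an enzyme of glycogen synthesis, rose by 1.45 ± 0.26 and the respiratory complex III subunit UQCR-11 by 1.21 ± 0.22. Without Canton-S 1 these 3 list calls were lost (medians 0.03, 0.06 and -0.02; adjusted p = 0.135, 0.126 and 0.710) and 1 glycolysis gene rose, and the last was also lost without Act88FKM88 1. The glycolysis median was 0.10 without Act88FKM88 2, and that of oxidative phosphorylation 0.25 without Canton-S 2 or Canton-S 3. Fatty acid oxidation genes were not called (adjusted p = 0.073).

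Among markers of other tissues, the cuticle and epidermis list was the only 1 called in Act88FKM88, lower than other genes (0 of 107 rose and 3 fell, 5 without Canton-S 2; median -0.08, adjusted p = 0.00171 and 0.536 with an estimated correlation). Cpr76Bd fell by 2.22 ± 0.22 and Cpr64Aa by 2.42 ± 0.46, the latter not called without Canton-S 1 (adjusted p = 0.103). Markers of fat body, hemocytes, gut, neurons and glia, tracheae, testis and accessory gland, head and eye, and odorant-binding genes were not called (lowest adjusted p = 0.058, neurons and glia). In these 8 lists 2 genes rose, FASN1 (1.07 ± 0.27) and Obp99c (1.45 ± 0.37), and none fell. FASN1 lost its call without Canton-S 1, Canton-S 2, any Act88FKM88 array or Mhc7 3 (adjusted p up to 0.260), and Obp99c when any array except Canton-S 3 was left out (adjusted p up to 0.248). Turandot and JAK-STAT genes, integrin and matrix genes, actin dynamics genes and clock genes were not called either (lowest adjusted p = 0.159), with the tubulin gene betaTub56D the only member past the threshold (-1.42 ± 0.33); it was not called without Canton-S 1, Canton-S 2 or Act88FKM88 1 (adjusted p up to 0.174).

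At an unadjusted p under 0.05, 2746 probe sets differed between Act88FKM88 and Canton-S. The ranges of the 2 genotypes did not overlap for 19.8% of all probe sets, against 10% by chance. They did not overlap for any of the 340 that passed, which the threshold itself favours. The count of 340 became 218 without Canton-S 1 and 176 with SAM. Without Act88FKM88 2, 213 were higher and 95 lower, against 278 and 62 with all arrays. Shares of higher calls rest on the deposited scale. The share was 81.8%, 51.0% with quantile normalization repeated (129 higher, 124 lower) and 24.8% with centring on cytosolic ribosomal protein genes, which moved the median of all genes by -0.51. With quantile normalization repeated, calls were lost for Mlp60A (0.71), Ubi-p5E (0.77), Atg8a (0.68), salr (0.94), mRpL33 (0.97), NLaz (3.17), CG14645 (3.38), FASN1 (0.99), Obp99c (1.16), stv (0.79), PEK (1.54), DnaJ-H and Prx6c, and with centring also for UGP (0.93), UQCR-11 (0.70), Calx (0.88) and kay (0.87). Repeated quantile normalization also ended the calls of the Z-disc (adjusted p = 0.7001), ubiquitin (0.952), autophagy (0.294), endoplasmic reticulum stress (0.294), detoxification (0.116) and calcium lists (0.994).

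The comparison of Mhc7 with Canton-S asked the same of muscle without its myosin heavy chain. All 26 proteasome subunits rose (median log2 difference 1.69), among them Prosbeta4 by 2.82 ± 0.27 and Prosalpha6 by 2.504 ± 0.30. Mitochondrial ribosomal protein genes rose in number, 50 of 69 with none falling (median 1.42), led by mRpL4 at 2.73 ± 0.30 and mRpL54 at 2.35 ± 0.22. The uncharacterized gene CG15617 fell by 8.49 ± 0.26, from 12.43 to 3.94, and pst rose by 5.12 ± 0.29, from 5.27 to 10.39. The Z-disc gene Zasp66 rose by 2.02 ± 0.13. In total 524 probe sets passed, 451 higher and 73 lower in Mhc7, for 427 genes.

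Further large rises in Mhc7 were CG32548 (3.50 ± 0.68), Cyp6a20 (3.44 ± 0.28, adjusted p = 0.000474), CG8768 (3.40 ± 0.36, adjusted p = 0.0015), the glutathione S-transferase gene GstD1 (3.30 ± 0.32, adjusted p = 0.00115), the mitochondrial translation release factor gene mRF1 (3.102 ± 0.34), CG4627 (2.59 ± 0.33) and the sorbitol dehydrogenase gene Sodh2 (2.56 ± 0.20). Further falls were SkpB (-4.25 ± 0.20, adjusted p = 2.77e-05), the seminal fluid protein gene Sfp53D (-3.74 ± 0.50), CG17298 (-3.07 ± 0.55), Cpr64Aa (-2.80 ± 0.46), CG42323 (-2.63 ± 0.44), l(2)34Fc (-2.61 ± 0.26) and gkt (-2.26 ± 0.13). Levels near the array median, where background limits the difference, were those of Sodh2 in Canton-S (3.26) and of SkpB (3.39), Sfp53D (2.84) and gkt (3.40) in Mhc7, beside Cyp6a20 and CG8768. The genes named up to here in this paragraph all kept their calls in the 9 fits that left out 1 array. CG7409 fell by 2.99 ± 0.69 (adjusted p = 0.0421), not called without Canton-S 2, Canton-S 3, Mhc7 2 or Mhc7 3 (adjusted p up to 0.147), and CG13314 fell by 2.59 ± 0.73 (adjusted p = 0.0901), not called when any array except Canton-S 3 was left out (adjusted p up to 0.264).

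In Mhc7, 12 of the 35 lists were called, 11 higher and 1 lower than other genes, none with an estimated correlation (lowest adjusted p = 0.412 with an estimated correlation) and 5 of them also by fry, which called the antioxidant list besides (adjusted p = 0.0123 by fry). The proteasome list had adjusted p = 4.13e-29 (0.412 with an estimated correlation, 0.0118 by fry), and 26 subunits passed when adjusted over the list alone. Ubiquitin genes were called (2 of 14 rose, median 0.46, adjusted p = 0.000286 and 0.412 with an estimated correlation), with TER94, the AAA ATPase that extracts ubiquitinated proteins, at 1.99 ± 0.16 and a list median of 0.28 without Canton-S 1. Constitutive chaperones were called (5 of 23 rose, 6 adjusted over the list alone; median 0.39, adjusted p = 0.000286 and 0.475 with an estimated correlation), among them Hsc70-4 at 1.38 ± 0.20. The chaperone count of 5 became 2 without Canton-S 1 or Mhc7 3, 3 without Canton-S 2 (median 0.22) and 8 without Mhc7 1. Of 25 autophagy genes 3 rose, including Atg8a at 1.55 ± 0.21, and 1 without Canton-S 1, Mhc7 1 or Mhc7 3 (list adjusted p = 0.00215 and 0.412 with an estimated correlation). With quantile normalization repeated, the proteasome list stayed called (13 rose, median 1.16), whereas the ubiquitin, chaperone and autophagy lists did not (adjusted p = 0.795, 0.167 and 0.167); with intensity trends removed the chaperone list was called (adjusted p = 0.0321, 0 rose) and the other 2 were not. The hybridization spike-in controls, bacterial transcripts added before hybridization, also lay higher in every Mhc7 array (mean log2 11.25 ± 0.12, SD, n = 3) than in Canton-S (10.20 ± 0.41; exact permutation p = 0.1).

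The mitochondrial ribosomal protein list had adjusted p = 1.58e-42 in Mhc7 (0.412 with an estimated correlation, 0.0159 by fry), and 55 genes passed when adjusted over the list alone. Per array, its mean log2 level was 7.77, 7.62 and 8.20 in Canton-S, 8.18, 8.67 and 7.88 in Act88FKM88 and 8.86, 9.55 and 9.24 in Mhc7. With quantile normalization repeated the list stayed called with 11 genes higher (median 0.72). Cytosolic ribosomal protein genes had a median of 0.36 with 0 of 34 past the threshold (adjusted p = 2.46e-05 and 0.654 with an estimated correlation), among them RpL27 at 0.70 ± 0.14. Tricarboxylic acid cycle genes (0 of 13, median 0.41, adjusted p = 6.05e-05 and 0.475 with an estimated correlation), oxidative phosphorylation genes (1 of 73, median 0.27, adjusted p = 9.09e-06 and 0.659) and glycolysis and glycogen genes (0 rose and 1 of 20 fell, median 0.28, adjusted p = 0.00435 and 0.648) were called higher. Quantile normalization repeated turned the cytosolic ribosomal, oxidative phosphorylation and glycolysis lists to the lower side (adjusted p = 0.946, 0.946 and 0.567) and ended the tricarboxylic acid cycle call (adjusted p = 0.995), which turned to the lower side with intensity trends removed (adjusted p = 0.111). Under trend removal the first 3 lists were called lower than other genes (adjusted p = 0.00187, 2.44e-08 and 0.0118). Without Canton-S 1 the glycolysis call was lost (median 0.14, adjusted p = 0.071), and the cytosolic ribosomal and oxidative phosphorylation medians were 0.13 and 0.10. The 1 oxidative phosphorylation gene that rose was not called without Canton-S 2 or Mhc7 3. AGBE, the glycogen branching enzyme gene, was the member that fell (-1.38 ± 0.31), not called without Canton-S 2, Canton-S 3 or Mhc7 3 (adjusted p up to 0.132).

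Of the sarcomere lists in Mhc7, 3 of 15 Z-disc genes rose (median 0.64, adjusted p = 0.00734 and 0.475 with an estimated correlation), including Zasp66 and the formin gene Fhos (1.18 ± 0.17); without Canton-S 1 the median was 0.37, and without Canton-S 3 1 fell. Of 12 thick and connecting filament genes 1 rose (2 adjusted over the list alone; median 0.37, adjusted p = 0.000619 and 0.475 with an estimated correlation). That member was the myofilin gene Mf (1.22 ± 0.25), whose call was lost without Canton-S 1 or Mhc7 3 (adjusted p up to 0.111) and whose second probe set gave -1.27; 2 members rose without Canton-S 3 or Mhc7 1. Quantile normalization repeated ended both list calls (adjusted p = 0.795 each), and with intensity trends removed the thick filament list turned to the lower side (adjusted p = 0.235). Thin filament genes were not called, with 0 of 12 past the threshold and the flight muscle troponin C gene TpnC4 at -0.68 ± 0.12 (adjusted p = 0.0111). Regulators of flight muscle fate and isoforms of other muscle types had 0 genes past the threshold (adjusted p = 0.562 and 0.867).

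Detoxification genes were not called as a list in Mhc7 (6 of 52 rose; median -0.00, mean 0.31, adjusted p = 0.444), and GstD1 and Cyp6a20 were the largest rises among them. Of 18 antioxidant genes 5 rose (3 without Canton-S 1, Canton-S 2, Mhc7 2 or Mhc7 3; 6 adjusted over the list alone; list adjusted p = 0.0875), among them the glutathione peroxidase gene Gtpx (1.73 ± 0.18). Sesn, a stress-induced regulator of growth signalling, was the 1 of 19 JNK and cell death genes that rose (1.60 ± 0.33), and Arc42 the 1 of 10 fatty acid oxidation genes (1.18 ± 0.22). Among the 9 measured of 23 inducible heat shock genes 1 rose, 0 without Canton-S 1 or any Mhc7 array, and 1 fell, 0 without Canton-S 2, Canton-S 3, Mhc7 2 or Mhc7 3. Among 11 actin dynamics genes 1 rose, 0 without Canton-S 1 or Mhc7 2 and 2 without Mhc7 1. Among 23 integrin and matrix genes none rose and 3 fell (list adjusted p = 0.0848), which became 0 without Canton-S 1, Canton-S 2, Act88FKM88 1, Mhc7 1 or Mhc7 3 and 1 without Act88FKM88 3 or Mhc7 2. Immune effectors, Turandot, endoplasmic reticulum stress, calcium and clock genes had 0 members past the threshold and were not called (lowest adjusted p = 0.0848).

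The cuticle and epidermis markers were again the only list of another tissue called, lower than other genes in Mhc7 (1 of 107 rose and 3 fell; adjusted p = 0.026 and 0.477 with an estimated correlation). Cpr76Bd fell by 2.17 ± 0.22, while Cpr66D rose by 1.39 ± 0.24. The list call ended with quantile normalization repeated (adjusted p = 0.237) and without Canton-S 3 (adjusted p = 0.0877) or Mhc7 1. In the other 8 marker lists 0 genes passed in Mhc7, and the lowest adjusted p was 0.0683, for testis and accessory gland.

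At an unadjusted p under 0.05, 3155 probe sets differed between Mhc7 and Canton-S, and the ranges of the genotypes did not overlap for 22.1% of all probe sets, against 10% by chance. Of the 524 that passed, 523 did not overlap, which the threshold itself favours. The 73 lower calls became 47 without Mhc7 3 and 102 without Canton-S 3. The share of higher calls was 86.1%, 54.1% with quantile normalization repeated (144 higher, 122 lower of 266) and 40% with centring on cytosolic ribosomal protein genes, which moved the median of all genes by -0.44. Fhos (0.48), Hsc70-4 (0.71), Atg8a (0.83), Arc42 (0.55), Sesn (1.13), Mf (0.62) and CG13314 (-2.89) lost their calls with quantile normalization repeated, and Cpr66D (0.95) with centring.

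**Figure D1:**
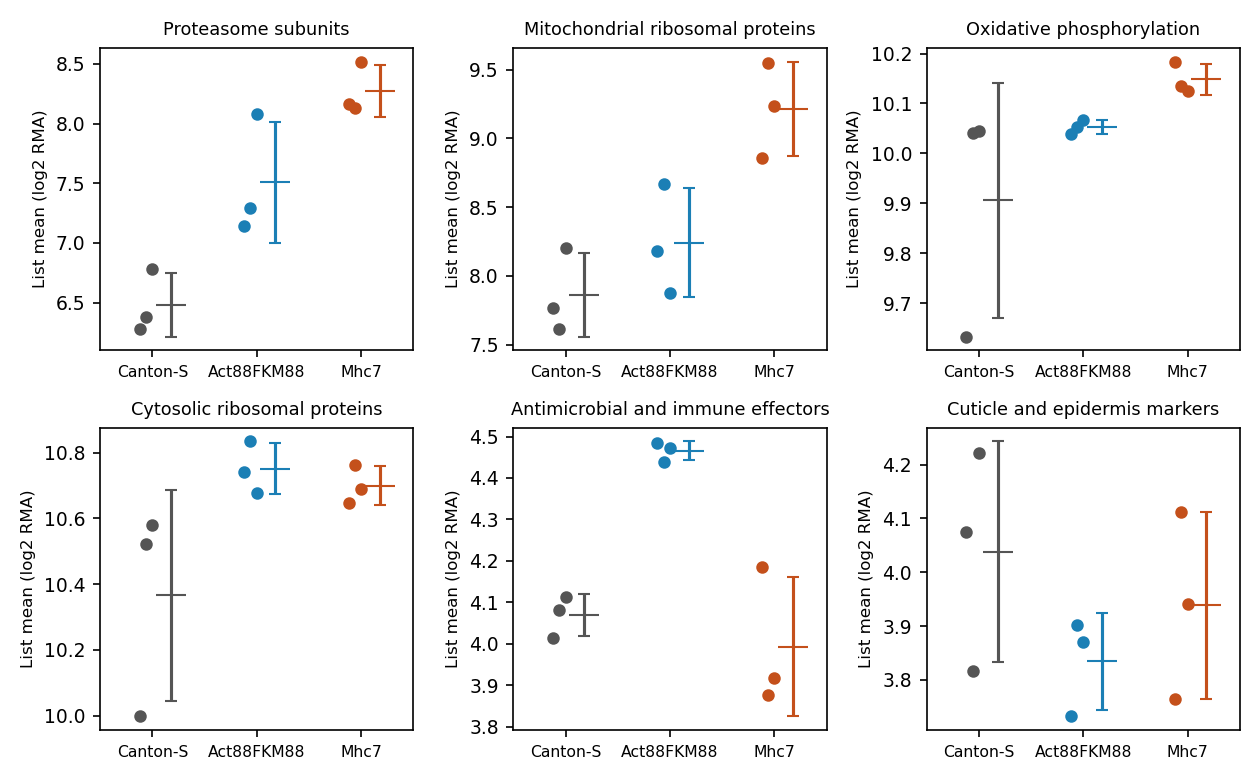
Mean log2 RMA level of 6 gene lists in each array of the 3 genotypes; points are arrays, and bars are means ± SD (n = 3). The proteasome list lies between 6.28 and 6.78 in Canton-S, 7.14 and 8.08 in Act88FKM88, and 8.13 and 8.52 in Mhc7, while cytosolic ribosomal and oxidative phosphorylation lists turn direction with quantile normalization repeated in Mhc7.

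**Figure D2:**
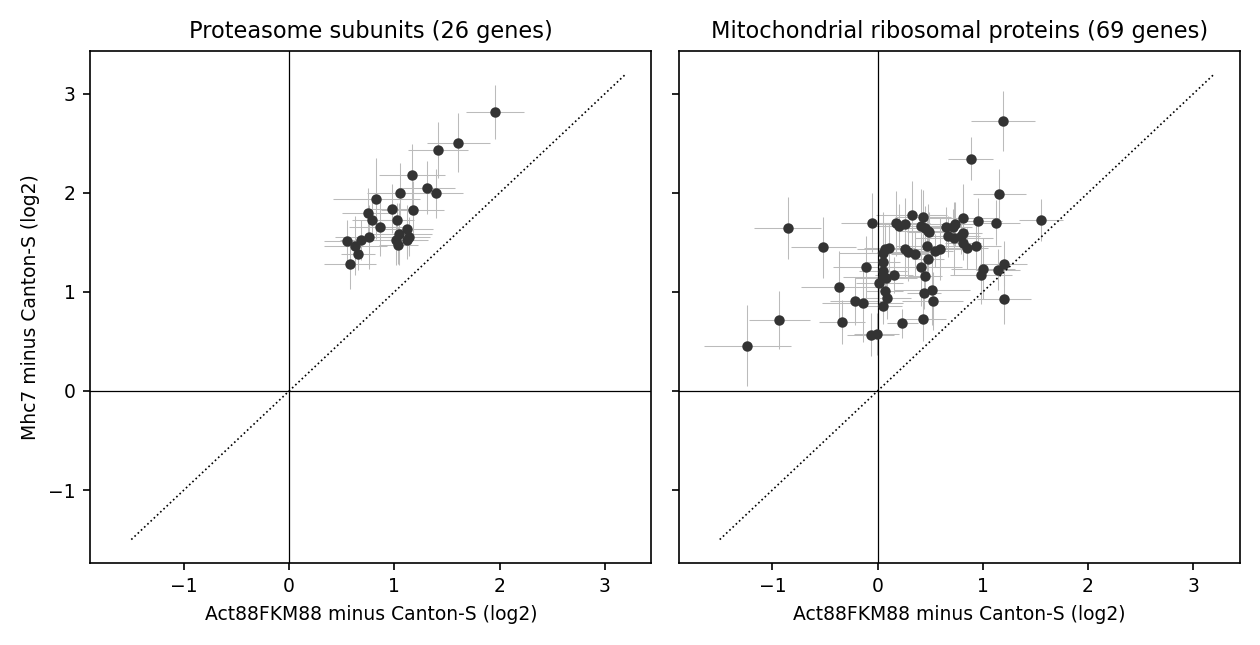
Log2 difference from Canton-S of each proteasome subunit gene (left) and mitochondrial ribosomal protein gene (right), Act88FKM88 on the horizontal and Mhc7 on the vertical axis, with SE; the dotted line marks equal change. Proteasome medians are 1.03 in Act88FKM88 and 1.69 in Mhc7 (0.71 and 1.16 with quantile normalization repeated), and mitochondrial ribosomal medians 0.43 and 1.42 (-0.00 and 0.72).

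The direct comparison of Act88FKM88 with Mhc7 asked where loss of actin and loss of myosin differ. Mitochondrial ribosomal protein genes were lower in Act88FKM88: 29 of 69 fell and none rose relative to Mhc7 (median -0.996), with mRpL21 at -2.5005 ± 0.32 and mRpS2 at -1.97 ± 0.31. Proteasome subunits were lower too, as a list (1 of 26 past the threshold, 4 adjusted over the list alone; median -0.80). With an estimated correlation both lists had adjusted p = 0.675, and by fry 0.151 and 0.169. CG15617 was higher in Act88FKM88 by 9.47 ± 0.26, and betaTub97EF and pst were lower, at -7.17 ± 0.13, a size limited by background, and -5.01 ± 0.29. The mitochondrial chaperone gene Trap1 was lower by -2.56 ± 0.20, and the Drosomycin-like genes Drsl5 and Drsl3 were higher by 2.05 ± 0.26 and 1.86 ± 0.21. In total 336 probe sets passed, 142 higher and 194 lower in Act88FKM88, for 276 genes.

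Sfp53D (4.19 ± 0.50), CG34324 (3.83 ± 0.47), Polr1E (3.68 ± 0.13) and SkpB (3.66 ± 0.20, adjusted p = 3.19e-05) were the other largest differences on the higher side, each with 1 mutant near the array median. Obsc (-3.66 ± 0.21, adjusted p = 4.14e-05), ppl (-3.39 ± 0.24), a subunit gene of the glycine cleavage system, and mRF1 (-2.95 ± 0.34) were the others on the lower side. Hsc70-4 was lower by -1.54 ± 0.20 and GstD3 by -1.64 ± 0.17, while Calx (1.91 ± 0.20), Ubi-p5E (1.32 ± 0.20), Cyp4e3 (3.19 ± 0.45) and the RNA-binding protein gene Hrb87F (1.45 ± 0.18) were higher. In these genes the calls were kept in all 9 fits that left out 1 array. The cuticle gene Cpr66D was lower by -2.81 ± 0.24 in Act88FKM88.

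Between the mutants, 7 lists were called, 3 on the higher and 4 on the lower side in Act88FKM88, and none with an estimated correlation (lowest adjusted p = 0.675 with an estimated correlation) or by fry. Mitochondrial ribosomal proteins (adjusted p = 2.36e-32; 34 genes adjusted over the list alone), proteasome subunits (1.03e-12) and constitutive chaperones (0 rose, 2 of 23 fell; median -0.34, 0.000692) were lower, and each had adjusted p = 0.675 with an estimated correlation. Immune effectors (4 of 26 higher, 5 adjusted over the list alone; adjusted p = 5.52e-05) and integrin and matrix genes (0 of 23 past the threshold, median 0.20, adjusted p = 0.000842) were higher, also at 0.675 with an estimated correlation. The calcium list (2 of 17 higher, 3 adjusted over the list alone; adjusted p = 0.0473 and 0.812 with an estimated correlation) was called higher and the oxidative phosphorylation list (0 of 73, median -0.10, adjusted p = 0.0473 and 0.928) lower. All but the last were also called with quantile normalization repeated, where oxidative phosphorylation had adjusted p = 0.0973. None of the other 28 lists was called between the mutants (lowest adjusted p = 0.0736, fatty acid oxidation), tissue markers included, and of 107 cuticle genes 1 fell.

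At an unadjusted p under 0.05, 2485 probe sets differed between the mutants, and ranges did not overlap for 18.2% of all probe sets, against 10% by chance. The count of 336 became 192 without Act88FKM88 1 and 213 without Mhc7 3. The 29 mitochondrial ribosomal protein genes became 6 without Act88FKM88 1, 12 without Act88FKM88 3, 12 without Mhc7 2 and 7 without Mhc7 3, and 16 with quantile normalization repeated. The 1 proteasome gene past the threshold, Rpt4 (-1.04 ± 0.25), lost its call when any array except Canton-S 3 and Act88FKM88 3 was left out (adjusted p up to 0.251) and with quantile normalization repeated (-0.80), while without Act88FKM88 3 15 subunits passed. The chaperone median of -0.34 became -0.14 without Mhc7 2, and the 4 immune genes became 2 without Act88FKM88 1, Mhc7 2 or Mhc7 3. Of integrin genes 2 rose without Act88FKM88 3 (median 0.36), and the 2 calcium genes became 1 without Act88FKM88 1, Act88FKM88 2 or any Mhc7 array. The integrin call was lost without Act88FKM88 2 (adjusted p = 0.066), the oxidative phosphorylation call without Act88FKM88 2, Act88FKM88 3 or Mhc7 1 (up to 0.240), and the calcium call without any Canton-S array, Act88FKM88 1, Act88FKM88 2 or Mhc7 1 (up to 0.223). The spike-in mean was 9.59 ± 0.13 (SD, n = 3) in Act88FKM88, below every Mhc7 array (exact permutation p = 0.1).

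The overlap of both mutants asked which transcripts change alike when either filament system is lost. Zasp66, Cyp6a20 and CG8768 rose at least 4-fold in both, and gkt, CG42323, Cpr64Aa and Cpr76Bd fell at least 4-fold in both. With quantile normalization repeated Zasp66 still passed, but under 4-fold (1.59 in Act88FKM88 and 1.45 in Mhc7). A second probe set of CG42323 gave -1.05 and -1.08. The other probe sets of gkt, with means of 3.07 and 2.61 near or below the array median, gave -1.29 and -1.04, and -0.05 and 0.05. In all, 124 probe sets passed in the same direction, 102 higher and 22 lower, which is 36.5% of the Act88FKM88 calls, and 17 of them changed at least 4-fold in both. Further genes among the 17, chosen after their values were seen, were kar (2.87 in Act88FKM88 and 2.31 in Mhc7), CG10383 (2.21 and 2.01), CG14270 (2.16 and 2.10) and CG11099 (2.07 and 2.01), which rose, and CG13920 (-2.07 and -2.06), which fell. The antioxidant gene Prx6c also rose in both (2.79 ± 0.64 and 2.24 ± 0.64), but its call was lost in Act88FKM88 without Canton-S 1, Canton-S 2 or Act88FKM88 1 (adjusted p up to 0.198) and in Mhc7 without Canton-S 1, Canton-S 2, Act88FKM88 1 or any Mhc7 array (up to 0.274). With quantile normalization repeated it was not called in either mutant (2.36, adjusted p = 0.125, and 1.59, adjusted p = 0.299).

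Opposite directions were found for 5 probe sets. ppl fell in Act88FKM88 and rose in Mhc7 (-1.77 and 1.62), as did Cpr66D (-1.42 and 1.39) and CG34015 (-1.64 and 1.03). CG18343 rose in Act88FKM88 and fell in Mhc7 (1.35 and -1.85), as did the cytochrome P450 gene Cyp28d1 (1.45 and -1.13). Of these, CG34015, CG18343 and Cyp28d1 were chosen after their values were seen.

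Independent lists of the same sizes would share 6.68 calls on the higher and 0.24 on the lower side, and simulations that kept the shared Canton-S arrays shared 0.01 on average and at most 1. The simulations held no effect in either mutant, so few probe sets could be called in them. The independent lists leave out the shared controls. Neither value therefore gives the overlap to be reached if each mutant changed in its own way. Changes in the mutants correlated across probe sets at r = 0.515 against 0.4998 in the simulations, with a covariance of 0.0707 against 0.0185, and 69.4% of probe sets had the same sign against 66.6%; probe sets are not independent replicates. Part of the overlap may come from the shared Canton-S arrays, which 3 controls are too few to divide. The 124 shared calls became 79 without Canton-S 1 and 192 without Canton-S 3, and 71 with quantile normalization repeated. The sets past the threshold in 1 mutant alone numbered 211 in Act88FKM88 and 395 in Mhc7, which by itself does not show a difference between the mutants.

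**Figure D3:**
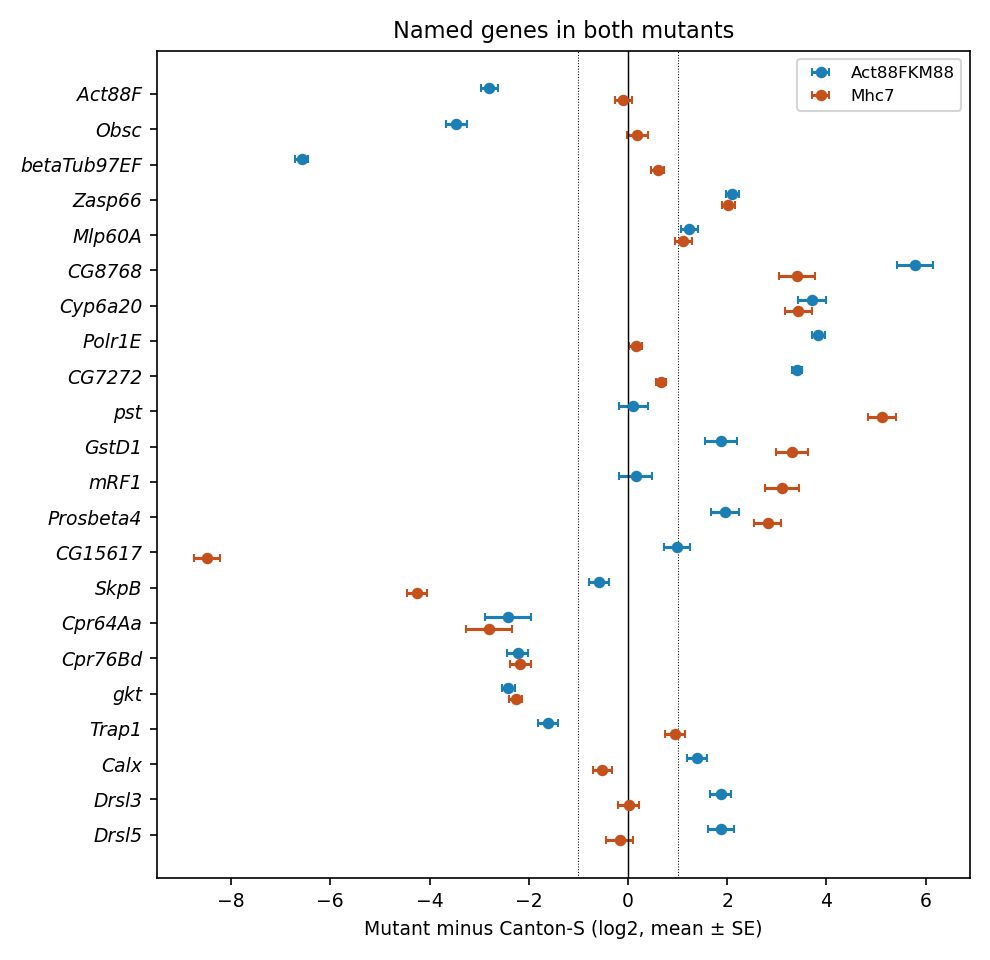
Log2 difference from Canton-S (± SE, n = 3 per genotype) of named genes in Act88FKM88 and Mhc7, with dotted lines at a 2-fold change. Act88F lies at -2.80 in Act88FKM88 and -0.10 in Mhc7, and Zasp66 at 2.11 and 2.02.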

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

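The tests of array scaling, spike-in controls, hybridization batch and strain background were chosen after the results were seen, and those of genes near the mutated loci before. The 18 hybridization spike-in probe sets, outside every comparison of genes, averaged a log2 level of 11.25 in Mhc7 against 10.20 in Canton-S and 9.59 in Act88FKM88, and were singled out because a signal outside the main measurement lay above its level in the control arrays.

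The proteasome list was called higher in both mutants (13 and 26 of 26 subunits rose; adjusted p = 0.536 and 0.412 with an estimated correlation), while abundant gene lists moved with the level of their genes. Against 10000 random lists of genes of the same level, the median change of the proteasome list lay at percentile 100 in both mutants, and the list stayed called with intensity trends removed (3 and 19 rose, medians 0.73 and 1.23), which argues against level-dependent scaling as its whole cause. Spike-ins were lower in Act88FKM88 than in Canton-S while the proteasome list was higher by 1.02. That argues only against an offset of the same sign carried into gene levels there. A technical difference that lowers spike-ins and raises gene signal was not tested. In Mhc7 the lowest spike-in mean lay 0.57 above the highest Canton-S mean. Spike-in means of Act88FKM88 (9.45 to 9.69) and Canton-S (9.76 to 10.58) did not overlap either, and Mhc7 lay at 11.15 to 11.38. A hybridization batch therefore cannot be told apart from genotype in any of the comparisons, for the proteasome list as for other genes. For glycolysis (percentile 8.35 in Act88FKM88, 10.7 in Mhc7), tricarboxylic acid cycle (26.9, 69.0), oxidative phosphorylation (12.7, 9.08), mitochondrial ribosomal genes in Act88FKM88 (43.0) and cytosolic ribosomal genes in Mhc7 (74.8), genes of the same level moved as far, so scaling could account for those calls. It could do so too in Act88FKM88 for thick filament (58.7), Z-disc (64.2), ubiquitin (83.1) and autophagy genes (91.5). There it also holds for endoplasmic reticulum stress (93.1) and calcium genes (46.3). The same holds in Mhc7 for thick filament (40.9), ubiquitin (81.0) and cuticle genes (4.92). Between the mutants it holds for oxidative phosphorylation (10.3). The tests disagreed for immune genes in Act88FKM88 (percentile 96.1), chaperones in Mhc7 (88.2) and calcium genes between the mutants (96.7). Some random lists moved as far, but these lists stayed called with trends removed (adjusted p = 0.0381, 0.0321 and 0.0114). With quantile normalization repeated only the calcium list stayed called (adjusted p = 0.0531, 0.167 and 0.00799). Scaling is left open for these calls. Cytosolic ribosomal genes in Act88FKM88 cannot be told apart from scaling, since they lay at percentile 100, trend removal ended their call (median 0.43 before and 0.05 after, adjusted p = 0.124), and repeated quantile normalization kept it (median 0.09, adjusted p = 0.00116); a response of muscle to loss of a filament stays open and untested.

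Of 69 mitochondrial ribosomal protein genes 50 rose in Mhc7, and 29 were lower in Act88FKM88 than in Mhc7. Their median change in Mhc7 lay at percentile 100 of lists of the same level, and the list stayed called with trends removed (24 of 69 rose, median 0.92), which argues against level-dependent scaling as the whole cause. With an estimated correlation between genes the list was not called (adjusted p = 0.412 in Mhc7 and 0.675 between the mutants). A hybridization batch that follows genotype cannot be told apart from genotype, because the lowest Mhc7 spike-in mean lay 0.57 above the highest Canton-S mean and the labels give no batch. A response to the loss of myosin stays open and untested.

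Several genes changed at least 4-fold in a mutant, such as CG15617 and betaTub97EF. A haplotype carried along with each mutation would place such genes near it: of the 200 measured genes nearest Act88F 0 changed 4-fold (one-sided Fisher's exact p = 1), and of those nearest Mhc 2 did, mRpL4 and Prosbeta4 (p = 0.205). Only 0.774 and 0.841 such genes would be found there by chance, so these tests had little power and the bound set beforehand was too easily met. The arms held no excess either, with 6 of 46 such genes on 3R in Act88FKM88 (13% against 25% of all genes, one-sided Fisher's exact p = 0.985) and 8 of 50 on 2L in Mhc7 (16% against 18.5%, p = 0.733), but for single genes a carried haplotype cannot be told apart from an effect of the mutation. The 17 probe sets changed 4-fold in the same direction in both mutants are what a difference of Canton-S from the mutant stocks would give, and also what a shared muscle response would give, which these 3 genotypes cannot tell apart.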

How the results depend on the processing

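The intensity trend removal was chosen after the data were seen; all other settings were planned. Of 228 named-gene values, those that held their direction and side of the threshold numbered 215 of 215 without dim probe sets, 210 on the 6 arrays of each pair, 219 with an intensity-dependent prior, 224 with array weights, 182 with ribosomal centring, 185 with quantile normalization repeated, 221 with the mean over probe sets and 223 with a replicate block. Of 34 called list results, 28 held without dim probe sets, 28 with centring, 32 with the gene mean, 33 with a replicate block, 11 with quantile normalization repeated (15 lost, 8 reversed) and 12 with trends removed (13 lost, 9 reversed).

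Looser thresholds raised the counts by construction: with no minimum fold 953 probe sets passed in Act88FKM88, 1334 in Mhc7, 740 between the mutants and 459 in both alike, and at 1.5-fold 735, 1010, 604 and 353. The treat test against 1.5-fold left 72, 178, 87 and 23. SAM called 176 in Act88FKM88, 175 of them shared with limma. Centring on cytosolic ribosomal protein genes gave 512 in Act88FKM88, 512 between the mutants, 192 in both alike and 9107 in the F-test, and turned Idh3g (-0.059), ScsbetaA (-0.12), trol (-0.086), Hml (-0.16), ProtA (-0.37) and rdgB (-0.37) in Act88FKM88 and salr (-0.074) and chp (-0.20) in Mhc7, none of them called. Quantile normalization repeated gave 266 in Mhc7, 71 in both alike, and 4 lists in Act88FKM88 and 3 in Mhc7. It turned sals (-0.10) and crc (-0.25) in Mhc7, uncalled, and the lists of thick filament (adjusted p = 0.944), glycolysis (0.931), tricarboxylic acid cycle (0.703), oxidative phosphorylation (0.0531) and mitochondrial ribosomal genes (0.994) in Act88FKM88, and of glycolysis (0.567), oxidative phosphorylation (0.946) and cytosolic ribosomal genes (0.946) in Mhc7. Trend removal gave 293 in Mhc7, 64 in both alike and 7 lists in Act88FKM88, and turned thick filament (0.089), glycolysis (0.242), tricarboxylic acid cycle (0.0381) and oxidative phosphorylation (2.64e-10) in Act88FKM88, and thick filament (0.235), glycolysis (0.0118), tricarboxylic acid cycle (0.111), oxidative phosphorylation (2.44e-08) and cytosolic ribosomal genes (0.00187) in Mhc7. The mean over probe sets gave Mf -0.026 in Mhc7, where its probe sets differ in sign. An estimated correlation left 0, 0 and 0 lists and fry 0, 5 and 0 of those called. For the shifts with centring, quantile normalization, trend removal, SAM and the list tests, the cause was not tested.

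With 1 array left out, counts ranged from 218 to 390 in Act88FKM88, 396 to 648 in Mhc7, 192 to 400 between the mutants, 79 to 192 in both alike and 1092 to 1624 in the F-test, and called lists from 11 to 20, 11 to 14 and 5 to 9. Without Canton-S 1 oxidative phosphorylation in Act88FKM88 turned (adjusted p = 0.710, lowest 9.38e-06 without Canton-S 2). Residuals of arrays with the same replicate number correlated over 0.1 in 3 of 9 pairs (-0.32 to 0.43, and -0.38 to 0.27 across numbers). The highest value, 0.43, was between Act88FKM88 2 and Mhc7 2, so pairing by number was neither established nor excluded. A block by number gave 345, 532, 340 and 137 probe sets. It ended 5 named-gene calls, among them stv, PEK and FASN1 in Act88FKM88, and 1 list call. Signal near background limits what can be seen for dim genes, whose values were kept in the tests.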

Other observations

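The added gene lists were chosen after the data were seen, while the other splits of the arrays were planned tests. Adjusted p-values of the added lists cover these few lists alone, not the larger set of planned lists. They therefore cannot be compared directly with the adjusted p-values of the planned lists. In Mhc7, 5 of 16 mitochondrial protein import genes rose (median 0.65, adjusted p = 2.68e-06 and 0.0583 with an estimated correlation), with a median of 0.12 when quantile normalization was repeated (adjusted p = 0.00117 and 0.0546) and 0.23 with intensity trends removed (0.000207 and 0.0479). Of 40 translation initiation factor genes 5 rose in Mhc7 (median 0.42, adjusted p = 6.16e-10 and 0.0583 with an estimated correlation), and repeated quantile normalization left a median of 0.04 (adjusted p = 0.149 and 0.377), but trend removal kept the call (0 rose, median 0.14, adjusted p = 0.00205 and 0.0479). Of 18 aminoacyl-tRNA synthetase genes 3 rose (median 0.54, adjusted p = 4.58e-05 and 0.148 with an estimated correlation; with quantile normalization repeated the median was 0.31, with adjusted p = 0.00117 and 0.179, and with trends removed 0.34, 0.000624 and 0.13).

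Mitochondrial aminoacyl-tRNA synthetases had 1 of 14 genes higher in Mhc7 (median 0.31, adjusted p = 0.000355 and 0.174 with an estimated correlation) and were lower in Act88FKM88 than in Mhc7 as a list (median -0.37, adjusted p = 1.72e-05 and 0.16 with an estimated correlation; -0.36, 9.86e-06 and 0.0754 with quantile normalization repeated). The V-ATPase list, for the proton pump of lysosomes, was higher in Act88FKM88 (3 of 31 rose, median 0.29, adjusted p = 0.000101 and 0.0845 with an estimated correlation; median 0.10, 0.0135 and 0.627 with quantile normalization repeated) and in Mhc7 (1 of 31, median 0.17, adjusted p = 0.000766 and 0.069; 0.03 and 0.814 with quantile normalization repeated). With trends removed the V-ATPase list had adjusted p = 0.00423 in Act88FKM88 (0.495 with an estimated correlation) and 0.149 in Mhc7, and mitochondrial synthetases 0.000436 in Mhc7 (0.13) and 5.85e-06 between the mutants (0.0741).

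Other splits of the arrays were counted for each result. Of 100 drawn splits of the 9 arrays into 3 groups of 3, the real 1 alone gave as many as 1654 probe sets in the F-test, with 730 the highest of the others. Chance is therefore an unlikely source of that count, but 100 splits do not exclude it. For shared calls, 2 of 100 splits gave 124 or more. The highest other, 141, divides the arrays by genotype too, with a mutant in the place of the controls. These splits can show that the 3 groups of arrays differ, whether by genotype or by a hybridization batch that follows it. They cannot show that the 2 mutants change alike, since a mutant as the shared reference gave a larger overlap. For single comparisons the 10 splits of 6 arrays are too few for a share under 0.05: the real split alone gave 340 in Act88FKM88 (highest other 0), 524 in Mhc7 (0) and 336 between the mutants (1). List counts of 15, 12 and 7 were reached by 3, 2 and 3 of the 10 splits, with 17, 13 and 11 the highest others, so camera with a preset correlation also calls lists in groups that mix genotypes.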
